A study of Mytilus galloprovincialis with 12 samples.

How the data were processed

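RNA from pooled digestive glands of the Mediterranean mussel, Mytilus galloprovincialis, was measured on 12 arrays, 4 from control mussels, 4 from mussels exposed to ketoprofen and 4 from mussels exposed to nimesulide. Each array held 1 pool of 3 glands, per the labels. Group membership was taken from the stress label of each sample, and replicates were numbered within a group only to name them, so no array was paired with another by its number.

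The scanner files hold a linear intensity for each spot, deposited by the authors as processed signal, which is background-subtracted and multiplicatively detrended, with a surrogate value in place of spots too dim to measure. Per the file headers, the arrays were read with scanner G2505C at 2 micron with an extended dynamic range and extracted with Feature Extraction 11.5.1.1 under protocol GE1_1105_Oct12. The series text names another scanner, G2565BA, and version 10.7.3.1, and the disagreement was left open. Each array carried 59971 probes of 60 bases and 1319 control spots, of which 308 were negative controls. The deposited value table holds log2 values of the same arrays, with medians from 5.17 to 5.57 per array. Its steps of normalization are not given in the sources used here. Set against log2 scanner intensity, its columns correlated with r from 0.974 to 0.997, so scale and direction were known while the centring between arrays was not. The median of the table was 5.53 for control replicate 1, 5.53 for replicate 2, 5.53 for replicate 3 and 5.53 for replicate 4. It was 5.52, 5.52, 5.51 and 5.52 for ketoprofen replicates 1 to 4, and 5.43, 5.40, 5.17 and 5.57 for nimesulide replicates 1 to 4. The table served only as an alternative.

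From the scanner files, log2 of the processed signal was taken, and the 75th percentile of log2 signal over all non-control probes was subtracted on each array. A probe was tested if it was well above background on at least 4 of the 12 arrays, whatever their group, which left 38271 probes. Values marked by the extraction software as non-uniform (98 values) were left out. It marked 0 values as population outliers and 0 as saturated. Group means were fitted over all 12 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, which left 9 residual degrees of freedom, and the 3 pairwise contrasts were tested two-sided. Adjusted p-values are Benjamini-Hochberg values over all tested probes, with a threshold of 0.05. The fold of a probe that was not well above background on any array of the dimmer group is given as a lower bound. For it, the mean of the brighter group was set against the mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. The bound allows for the floor of the processed signal but not for the spread between pools, and other processing gave smaller differences.

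The fit was tested on simulated data drawn from the measured means and residual spreads of the 38271 probes. Of 200 probes changed 2-fold between ketoprofen and control, 0% were recovered, against 36.0% of those changed 4-fold and 63.0% of those changed 8-fold. For nimesulide against control the shares were 0%, 41.0% and 67.0%, and for nimesulide against ketoprofen 0%, 40.5% and 72.0%. With no probe changed, limma called 1 probe between nimesulide and ketoprofen, as many as in the data. With changed probes, false calls numbered up to 8 for ketoprofen against control, 6 for nimesulide against control and 9 for nimesulide against ketoprofen. The number of arrays limits the precision, and the median 95% half-width of a fold change was 0.94 on the log2 scale, a factor of 1.92.

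No probe carried a gene name in the files, whose description reads unknown for each of the 59971 probes, and the reference table pairs gene identifiers with symbols but holds no sequences, so 0 probes were named. The 25 gene lists fixed before the data were examined, with markers of haemocytes, gonad, muscle, cilia and foot among them, were therefore not tested, and neither was cyclooxygenase, the known target of these drugs. The rule fixed for that case allowed at most 2 probes higher and 2 lower per comparison, which were taken as those with the smallest p. Each is given with its identifier and sequence. To describe groups of related transcripts in place of the lists, probes were joined into families by their sequences alone with blastn of BLAST+ 2.17.0 (alignments of at least 40 bases at 85% identity or more, word size 11). A chain of such alignments was enough, so members of a family need not resemble each other directly, and the largest held 145 probes. Both strands were searched, so a family can hold probes for opposite strands, and its mean can mix their signals. The 345 families with at least 5 tested probes held 3348 probes, and the mean log2 value of each was fitted as the probes were. This grouping was chosen after the data were seen.

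Alternatives covered the background correction (normexp with an offset of 50), quantile, median and cyclic loess normalization, filters on dim probes and outlier marks. They also covered the variance model, array weights, the slide, the value table, the arrays in the fit, the thresholds and leaving out each array. Normexp was run on the mean signal in place of the processed signal, so both the signal and the background step changed with it. The offset of 50 by itself shrinks the differences of dim probes. A smaller difference of such a probe with normexp is therefore built into the setting and is no independent check. The headers place all control and all ketoprofen arrays on slide 1. Nimesulide replicates 1 and 2 were on slide 2 and replicates 3 and 4 on slide 3, and each slide was a scan run of its own. Nimesulide and slide therefore cannot be told apart in any contrast with nimesulide, while ketoprofen and control were compared within 1 slide. On it, all control arrays lay in row 1 and all ketoprofen arrays in row 2, so ketoprofen and row cannot be told apart. The series text names 3 tanks of 17 L for the 3 groups, and how the pools were spread over tanks is not given in the sources used here. If each group was held in 1 tank, drug and tank cannot be told apart in any of the 3 contrasts. The p-values measure the spread between pools, not that between tanks.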

Results

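Mussels were acclimated for 10 days and then exposed for 14 days to 0.5 µg/L of ketoprofen or of nimesulide, or kept as controls with a trace of methanol (0.00001%). Both drugs are non-steroidal anti-inflammatory drugs, which block the cyclooxygenases that make prostaglandins. The series title places the work in the assessment of toxicological risk of such drugs to marine mussels, and the arrays address whether transcription in the digestive gland, the main organ of digestion and detoxification in bivalves, differed after exposure. The labels disagree on salinity, with 37 ‰ in the series text and 28 to 30 ‰ in those of the samples.

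The share of the 59971 probes well above background was 62.6% to 65.1% on the control arrays, 50.1% to 62.4% on the ketoprofen arrays and 32.1% to 60.5% on the nimesulide arrays. The median processed signal was between 26.2 and 71.4 intensity units on the 12 arrays. Negative control spots, which match no mussel transcript, were 2.08 higher on the log2 scale on nimesulide than on control arrays after scaling, and 1.21 higher on ketoprofen than on control arrays. Probes with identical sequences differed within an array by a median SD of 0.06 (log2), while the same probes had a median residual SD of 0.45 between pools. Over all tested probes, pools of a group differed by a median SD of 0.52 for control, 0.60 for ketoprofen and 0.53 for nimesulide. The first principal component held 19.0% of the variance, and control replicate 1 (-190.4), ketoprofen replicate 1 (-152.6) and ketoprofen replicate 4 (-70.9) lay at its negative end.

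**Figure D1:**
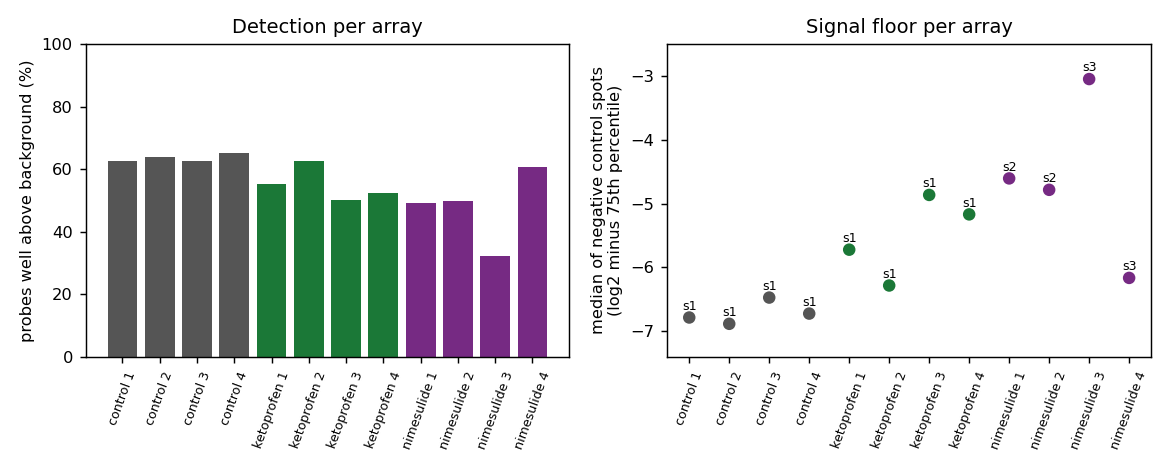
Left, bars of the percentage of probes well above background on each of the 12 arrays. Right, the median of the 308 negative control spots of each array (log2 signal minus the array's 75th percentile), with s1 to s3 naming the slide. Nimesulide replicate 3 had the highest floor (-3.05) and the lowest share of detected probes (32.1%).

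Ketoprofen against control asked for the response to the first drug. The probes with the smallest p lay far apart between the groups, though none passed the threshold. ALL2_REP_C94079_AS (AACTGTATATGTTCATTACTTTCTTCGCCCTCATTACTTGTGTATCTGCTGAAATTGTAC) was well above background in all 4 control pools, at 0.70 ± 0.72 on the scaled log2 axis (SD, n = 4), and in none of the ketoprofen pools, at -4.37 ± 0.50. By the bound it was at least 17.6-fold lower with ketoprofen, or 4.13 on the log2 scale. Normexp with an offset of 50 gave a smaller log2 difference, -2.39. The ketoprofen signals of this probe were 6.02 to 30.3 units, so the offset alone shrinks the difference. ALL2_C62272_P (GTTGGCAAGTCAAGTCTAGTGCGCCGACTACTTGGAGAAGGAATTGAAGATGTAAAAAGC) showed the opposite, at -1.32 ± 1.33 with ketoprofen and not well above background in any control pool (-6.64 ± 0.29). By the bound it was at least 10.1-fold higher, or 3.34 on the log2 scale, while normexp gave a smaller log2 difference, 1.94.

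ALL2_C65070_P (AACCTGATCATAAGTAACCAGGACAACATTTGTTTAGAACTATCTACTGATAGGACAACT) was at -1.11 ± 0.14 with ketoprofen and -4.86 ± 0.55 in controls, where 1 of 4 arrays measured it well above background, and with normexp the log2 difference was 1.58. ALL2_C74236_P (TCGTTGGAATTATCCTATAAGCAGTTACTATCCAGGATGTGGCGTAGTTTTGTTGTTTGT) was at -1.81 ± 0.57 in controls and -5.66 ± 0.62 with ketoprofen (SD, n = 4). By the bound it was at least 3.09-fold lower, or 1.63 on the log2 scale, while normexp gave a smaller log2 difference, -1.07. The adjusted p of limma was 0.112 for each of the 4 probes. In every one, the 4 ketoprofen pools lay on 1 side of the 4 control pools. Such separation is likely for probes chosen by the smallest p, here and below, and gives no further support.

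Over all 38271 tested probes, limma called 0 probes higher and 0 lower. At an unadjusted p under 0.05 there were 3193 probes, 1457 higher and 1736 lower. Independent probes without any change would give 1914, and other splits of the same 8 arrays gave as many as 4244. The groups did not overlap at 1641 probes (4.29%, chance 2.86%), and of those 298 were at least 2-fold higher and 433 at least 2-fold lower. The chance share is a mean, and its spread over other splits was not computed. The negative control median of every ketoprofen array (lowest -6.28) lay above that of every control array (highest -6.47). A probe at the floor in both groups can thus count as not overlapping. A fit of the 8 control and ketoprofen arrays alone, which lie on 1 slide, called 4 probes higher and 2 lower, among them ALL2_C65070_P and ALL2_REP_C94079_AS (adjusted p of limma 0.0128 each). The deposited value table called 7 higher and 9 lower, and all 4 named probes were among them (adjusted p of limma 0.00222 to 0.0112). Their log2 differences there were nearly those of quantile normalization, which called 0. For ALL2_C62272_P they were 4.32 and 4.33 (adjusted p of limma 0.00222 and 0.12). For ALL2_REP_C94079_AS both were -5.17 (0.00986 and 0.219). The lower adjusted p in the value table thus came without larger differences than with quantile normalization, and these calls add no separate support. Without nimesulide replicate 4 all 4 were called too (0.021 to 0.0448). Slide column as a block, chosen after the data were seen, called 0 (3318 at an unadjusted p under 0.05).

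Among families of probes with related sequences, limma called 0 of 345 with ketoprofen, and 30 had an unadjusted p under 0.05 (7 higher, 23 lower, where 5% is 17.2). Without control replicate 1 the count of calls was 5. The smallest p of all belonged to a family of 5 probes, all lower, with the brightest member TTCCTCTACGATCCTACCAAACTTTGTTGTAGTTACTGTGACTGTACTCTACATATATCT. Its adjusted p of limma was 0.24, and 0.0255 without control replicate 1. With ketoprofen 5 of its 20 values were well above background, against 19 of 20 in controls, and with normexp the difference was 0.0764. A family of 6 probes (brightest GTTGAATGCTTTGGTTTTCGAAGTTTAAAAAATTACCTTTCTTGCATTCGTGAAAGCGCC), was also lower (adjusted p of limma 0.398). With ketoprofen 1 of its 24 values was well above background, against 22 of 24 in controls, and with normexp its difference was 0.0801. Neither of these 2 dim families has a measured size of change. The family with the smallest p among those higher had 7 probes, all higher, and its brightest member read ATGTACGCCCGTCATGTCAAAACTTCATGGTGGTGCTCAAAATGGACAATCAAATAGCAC. Its mean was 2.33 (SE 0.56) above control on the log2 scale, a 5.03-fold difference (adjusted p of limma 0.24), and 2.80 without control replicate 1 (adjusted p of limma 0.0255). Another family of 6 probes (brightest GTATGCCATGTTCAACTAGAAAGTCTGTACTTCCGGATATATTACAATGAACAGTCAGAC) was at 1.52 (SE 0.41) above control, with an adjusted p of 0.381. All 6 of its probes were higher.

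Nimesulide against control asked the same of the second drug, with slide and group confounded, and 2 probes were called higher. ALL2_REP_C16001_P (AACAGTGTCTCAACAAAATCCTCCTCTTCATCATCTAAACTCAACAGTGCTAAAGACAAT) rose 9.13-fold, from -2.45 ± 0.49 in controls to 0.74 ± 0.58 with nimesulide (SD, n = 4), a log2 difference of 3.19 (SE 0.33, adjusted p of limma 0.0319). The difference was 2.26 with normexp and 0.57 in the value table. All 8 arrays measured it well above background, and each of the 4 nimesulide pools lay above each control pool. ALL2_C56279_P (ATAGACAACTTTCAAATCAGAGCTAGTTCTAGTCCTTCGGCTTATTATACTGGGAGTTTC) was not well above background in any control pool and was at -0.46 ± 1.53 with nimesulide, at least 18.3-fold higher (adjusted p of limma 0.0319). That bound is 4.20 on the log2 scale, and the log2 difference was smaller with normexp, at 2.69, and in the value table, at 2.02.

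In this fit limma called 0 probes lower with nimesulide, beside 984 lower at an unadjusted p under 0.05. It called 1 lower with quantile normalization, 3 in the value table and 76 without a filter on dim probes. ALL2_C62404_AS was the only lower call of the 8 arrays alone (adjusted p of limma 0.0331) and without ketoprofen replicate 3 (adjusted p of limma 0.0247). The smallest p among lower probes belonged to ALL2_C12863_P (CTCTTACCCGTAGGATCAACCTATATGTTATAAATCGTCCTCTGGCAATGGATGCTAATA), at -0.02 ± 0.37 in controls and -2.23 ± 0.36 with nimesulide, where 2 of 4 arrays measured it well above background (adjusted p of limma 0.19). The same probe was at -1.74 ± 0.45 with ketoprofen, a log2 difference of -1.72 from control (adjusted p of limma 0.353). ALL2_C62404_AS (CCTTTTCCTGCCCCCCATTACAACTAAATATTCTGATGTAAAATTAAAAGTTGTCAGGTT) was at 0.25 ± 0.29 in controls and -2.80 ± 0.33 with nimesulide, where 1 of 4 arrays measured it well above background (adjusted p of limma 0.323).

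At an unadjusted p under 0.05 there were 2523 probes, 1539 higher and 984 lower. Independent probes without any change would give 1914, and another split of the same 8 arrays gave 2649. In all, 1811 probes (4.73%, chance 2.86%) did not overlap between the groups. The limits given for ketoprofen hold here too, since every nimesulide array had a higher floor than every control array (lowest -6.17 against highest -6.47). Quantile normalization gave 1 probe higher and 1 lower and normexp 3 higher, and ALL2_C56279_P was not among them (adjusted p of limma 0.0702 and 0.0731), nor was it called with cyclic loess (0.146). The median of each array gave 0 calls (2996 at an unadjusted p under 0.05), and a fit of the 8 arrays alone gave 15 higher and 1 lower, without ALL2_REP_C16001_P (adjusted p of limma 0.0539). The deposited value table gave 3 higher and 3 lower, and 0 of the 2 probes above were among them. The call of ALL2_REP_C16001_P was lost in 7 of the 12 fits that left out 1 array, namely without control 1 or 2, ketoprofen 3 or 4, or nimesulide 2, 3 or 4. That of ALL2_C56279_P was also lost in 7, without control 1, 2 or 4, ketoprofen 3 or 4, or nimesulide 1 or 3. Adjusted p reached 0.222 for both, while the log2 difference stayed between 2.96 and 3.48 for the former.

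Limma called 0 of 345 families higher or lower with nimesulide, and 20 had an unadjusted p under 0.05 (17 higher, 3 lower, where 5% is 17.2). Without nimesulide replicate 3 the count of calls was 4, without a filter on dim probes it was 2, and with both changes it was 6. A family of 96 probes, whose brightest member read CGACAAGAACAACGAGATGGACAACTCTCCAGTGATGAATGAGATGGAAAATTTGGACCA, was bright in every group. It was at 2.62 ± 0.38 in controls, 2.85 ± 0.37 with ketoprofen and 3.91 ± 0.48 with nimesulide (SD, n = 4). Its difference between nimesulide and control was 1.30 (SE 0.30, adjusted p of limma 0.35), with 85 of its probes higher and 11 lower. It was 0.93 with normexp and 0.53 in the value table. Without nimesulide replicate 3 the difference was 1.51 (adjusted p of limma 0.0373), and over all alternatives its adjusted p lay between 0.0373 and 0.807. A family of 7 probes (brightest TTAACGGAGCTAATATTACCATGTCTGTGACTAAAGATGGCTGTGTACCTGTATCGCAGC) had a log2 difference of -1.30 (SE 0.53) and an adjusted p of limma of 0.666.

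**Figure D2:**
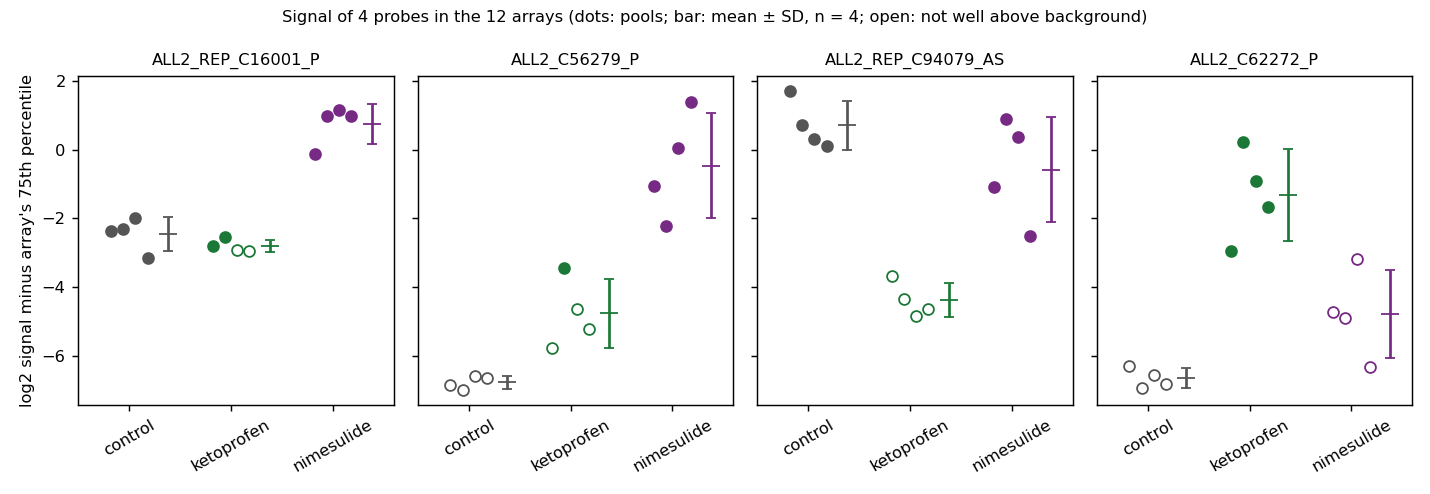
Scaled log2 signal (log2 minus the array's 75th percentile) of 4 probes in the 12 pools, by group, with filled dots for arrays well above background, open dots for the others, and the mean ± SD beside them (n = 4). ALL2_REP_C16001_P stood at 0.74 on average with nimesulide against -2.45 in controls, and ALL2_REP_C94079_AS at -4.37 with ketoprofen against 0.70 in controls.

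Nimesulide against ketoprofen compared both drugs at the same nominal concentration and time, and here slide and group were confounded. ALL2_REP_C16001_P was 11.6-fold higher with nimesulide (log2 difference 3.54, SE 0.33, adjusted p of limma 0.0129), and its level with ketoprofen was -2.80 ± 0.18 (SD, n = 4), where 2 of 4 arrays measured it well above background. It was the only probe called, and all 4 nimesulide pools lay above all 4 ketoprofen pools. ALL2_C56003_P (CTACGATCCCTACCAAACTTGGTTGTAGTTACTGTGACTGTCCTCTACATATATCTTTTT) was not well above background with ketoprofen and was so on 1 of 4 nimesulide arrays (adjusted p of limma 0.505), so no fold is given.

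On the lower side, ALL2_C62272_P was at -4.77 ± 1.28 with nimesulide, where no array measured it well above background, and at least 2.38-fold below ketoprofen (adjusted p of limma 0.575). That bound is 1.25 on the log2 scale, and normexp gave a log2 difference of -1.02. ALL2_REP_C23372_P (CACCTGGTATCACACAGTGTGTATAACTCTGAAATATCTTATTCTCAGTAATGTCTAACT) was at -2.79 ± 0.68 with nimesulide, well above background on 3 of 4 arrays, and -0.81 ± 0.50 with ketoprofen (SD, n = 4). Its log2 difference of -1.98 (SE 0.41) had an adjusted p of limma of 0.575.

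Limma called 1 probe higher and 0 lower, with 3003 at an unadjusted p under 0.05 (1745 higher, 1258 lower). Independent probes without any change would give 1914, and another split of the same 8 arrays gave 3901. The groups did not overlap at 1799 probes (4.70%, chance 2.86%), and the spread of this share over other splits was not computed. The call was lost without ketoprofen 3 or 4 or nimesulide 2, 3 or 4 (5 of 12 fits, adjusted p up to 0.101), with normexp (log2 difference 2.01) and with only the 8 arrays, and in the value table, where the log2 difference was 0.96. Quantile normalization added 1 lower call to the 1 higher one.

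Among families, limma called 2 higher with nimesulide than with ketoprofen and 0 lower (44 at an unadjusted p under 0.05, 39 higher and 5 lower, where 5% is 17.2). The first had 5 probes, all well above background on all arrays, and its brightest member read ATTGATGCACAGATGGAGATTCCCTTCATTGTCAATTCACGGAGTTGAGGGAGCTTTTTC. It was at 2.95 ± 0.21 with nimesulide, 1.76 ± 0.09 with ketoprofen and 2.28 ± 0.36 in controls (SD, n = 4), and the log2 difference between the drugs was 1.19 (SE 0.22, adjusted p of limma 0.0463). The second was the family of 5 probes with the smallest p between ketoprofen and control, and its adjusted p of limma was 0.0463. ALL2_C56003_P, described above, is 1 of its 5 probes, so probe and family are not separate observations. It compares values mostly near the signal floor, with 5 of 20 values well above background with ketoprofen and 7 of 20 with nimesulide, against 19 of 20 in controls, and it gives no size of change. Both calls were lost in 9 of the 12 fits that left out 1 array, with adjusted p up to 0.139. Those fits lacked control 3, any ketoprofen array or any nimesulide array, and the log2 difference of the first family stayed between 1.09 and 1.26. Of the other settings, the call of the first was lost in 6 of 10 and that of the second in 8 of 9, with adjusted p up to 0.997 in the value table. With normexp the adjusted p of limma was 0.265 and 0.38, and the difference of the first was 0.94.

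The responses to both drugs were set side by side across the 38271 probes, which are not independent replicates. The fold changes against control correlated with Pearson's r of 0.546 and Spearman's rho of 0.482. Groups without any effect that share the 4 control arrays gave a mean r of 0.500 in 100 simulations, from 0.479 to 0.523. The covariance was 0.359, against a simulated mean of 0.268 (0.254 to 0.287), a difference of 0.0903. When the controls were split 2 and 2, so that each drug had its own, the mean r over the 6 splits was 0.0326, from -0.0528 to 0.145. The mean covariance over these splits was 0.0258. At adjusted p, limma called 0 probes in both comparisons. At an unadjusted p under 0.05, 382 probes were higher and 293 lower with both drugs, where independent lists give 58.6 and 44.6, and simulations with shared controls gave 226.1 on average and at most 269 higher and 256 lower. Opposite directions were found for 4 probes, and the simulations with shared controls gave 6.40 on average, from 2 to 14. Simulated probes were independent, so these ranges do not allow for probes that vary together. The simulations also gave all groups the same spread per probe. They therefore do not allow for controls that vary more than the exposed pools, which alone would raise the covariance. With split controls the mean covariance, 0.0258, was smaller than the difference of 0.0903. The measured lists held 3193 and 2523 probes where 1914 are expected, and longer lists overlap more. The excess over the simulations is therefore no measure of a shared response.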

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

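The tests of the families, of the negative control spots, of detection among the called probes and of identical sequences, and the fit without a filter and without nimesulide replicate 3, were chosen only after the results were seen. Among 75 groups of 4 values examined, 5 held a sample far from the other 3, where chance gives about 3.75. ALL2_C65070_P was -1.32 in ketoprofen replicate 2, while the others lay between -1.07 and -1.02. ALL2_REP_C16001_P was -0.12 in nimesulide replicate 1, against 0.96 to 1.13 in the others, and that pool still lay above every control and ketoprofen pool. The dim family of 5 probes called between the drugs was -3.94 in ketoprofen replicate 2, against -4.29 to -4.25. The SD of the negative control spots' net signal was 7.88 on control replicate 1, against 2.89 to 3.66 on the other control arrays. It was 11.45 on ketoprofen replicate 1, against 3.81 to 4.77 on the other ketoprofen arrays. Both of those arrays sat in the same column of slide 1.

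Limma called a difference between the effects of the drugs, by the test of the difference itself, for ALL2_REP_C16001_P (3.54 on the log2 scale) and for a bright family of 5 probes (1.19). Leaving out 1 array ended the first call in 5 of 12 fits and the second in 9 of 12. As many probes were called in 9 of 35 splits of the arrays, so chance was not excluded for the probe, and no splits were run for families. The dim family of 5 probes passed the same test (1.37), but 15 of its 20 ketoprofen values and 13 of its 20 nimesulide values were not well above background, so it is not counted as a difference between the drugs. Its difference was 0.66 with normexp (adjusted p of limma 0.38). Nimesulide and slide were confounded in all 3.

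When dim probes were kept, limma called 8382 probes higher and 76 lower with nimesulide than in controls, and 8089 of the higher ones had failed the filter on dim probes. Their median rise was 2.08 on the log2 scale. The 308 negative control spots rose by a median of 2.08 as well (quartiles 2.03 and 2.12), so a higher signal floor on the nimesulide arrays is a candidate explanation for most of these calls. A rise of many weakly expressed transcripts was not excluded, since 11.1% of the called probes were well above background on more nimesulide than control arrays, between the bounds set for either reading. Without nimesulide replicate 3 the same fit called 0 probes, with 13691 at an unadjusted p under 0.05, against 16193 with all arrays. Its lowest adjusted p of limma was 0.0583, just over the threshold, and its median log2 difference was 0.31, against 0.38 with all arrays. The negative control spots still rose by a median of 1.54. The loss of calls is thus a matter of the threshold and does not speak against the floor as an explanation.

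Some probes were on in 1 pool of a group and off in another, with a range over 4 on the log2 scale and the lowest value not well above background. There were 3383 in the control group, 2640 in the ketoprofen group and 1703 in the nimesulide group, together 5121 probes or 13.4% of those tested. Noise of single spots was argued against by 82 comparisons with a probe of identical sequence on the same 2 arrays. In 98.8% of them the partner differed the same way by over 2 on the log2 scale. A pair of probes could be counted once from each side. The off values did not gather on 1 array, since control replicate 1, with the most, held 14.2% of those of all groups. This share cannot reveal an array that failed by a raised floor. Nimesulide replicate 3 had the highest floor and held the fewest off values (2.15%). Differences between pools of 3 glands in which transcripts are present may underlie the pattern, and no biological explanation was tested.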

How the results depend on the processing

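The slide column block, the fit without a filter and without nimesulide replicate 3, and the families were chosen after the data were seen. The 12 named fold changes and 12 family differences kept their direction in every setting run, except 2 family differences between ketoprofen and control that turned with normexp, from -1.15 to 0.0764 for the dim family of 5 probes and from -1.56 to 0.0801 for the family of 6 that was lower. These probes and families were chosen for a small p in the same data, so a kept direction is likely and adds little support. With normexp the offset by itself shrinks differences of dim probes and families. Where a count or value moved below, the cause was otherwise not tested. Called probes between ketoprofen and control numbered 0 in the design's fit, 6 with only the 8 arrays, 16 in the value table and 0 to 6 when 1 array was left out. Between nimesulide and control the 2 became 0 with the median of each array, with probes well above background on all 12 arrays (a filter that leaves both called probes untested), at an adjusted p under 0.01, and without a filter and nimesulide replicate 3. They became 1 with cyclic loess, 6 in the value table, 16 with only the 8 arrays, 8458 without a filter and 0 to 10 when 1 array was left out. Between nimesulide and ketoprofen the 1 became 0 with normexp, all 12 arrays above background (called probe untested), the value table, only the 8 arrays or an adjusted p under 0.01, 2 with quantile normalization, and 0 to 2 when 1 array was left out. These zeros are limma counts. They stood beside 1200 to 13691 probes at an unadjusted p under 0.05 for nimesulide against control, and beside 14 (value table) to 3003 for nimesulide against ketoprofen. The correlation of fold changes was 0.633 with normexp, 0.451 with quantile normalization, 0.707 without a filter, 0.961 in the value table, 0.0326 with split controls and 0.471 to 0.627 when 1 array was left out. Probes called with both drugs numbered 6 in the value table and 0 to 4 when 1 array was left out. The median difference between nimesulide and control was 0.02 in the design's fit and 0.22 with normexp background correction. It was -0.10 with quantile and -0.14 with median normalization. Slide as a random block (correlation -0.0573) gave 0, 2 and 1 calls, but it cannot separate slide from drug in a contrast with nimesulide. With it, the adjusted p of limma for ALL2_REP_C16001_P against control went from 0.0319 to 0.0168. Slide as a fixed block could be fitted only for ketoprofen against control (0 calls, 3048 at an unadjusted p under 0.05). Both groups lie on slide 1, so that block could not change their difference. Neither fit shows robustness to slide. The tests of gene lists were not run, since no probe had a gene name. Probes near the signal floor have no order within it, which limits every comparison of dim probes.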

Other observations

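The value table, quantile normalization and the fits of 8 arrays were planned settings, but their use below as tests of explanations was chosen after the results were seen, as was the alignment of slide means in scanner values. The splits of the arrays were first run on the 8 arrays compared and then, with that result seen, in the 12-array fit of the design.

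In the deposited value table, nimesulide and ketoprofen arrays were nearly alike. The SD over probes of their mean difference was 0.22, against 0.77 in scanner values, while that of ketoprofen and control was 0.78, against 0.82. The 2 nimesulide slides had also drawn together, with an SD of their difference of 0.22 against 0.89 in scanner values, a ratio of 0.253, while 2 arrays of 1 slide kept ratios of 0.929 and 0.786. Quantile normalization alone was argued against, since it left 3332 probes at an unadjusted p under 0.05 between the drugs. A shared response to both drugs was argued against as the whole cause, since the table gave 14 such probes where equal groups give 1914 by chance, and since the SD of 0.22 lay below the 0.44 to 0.66 of the 34 other splits of those 8 arrays. An alignment of all slide means was argued against as the whole cause. It would put nimesulide equally far from both other groups, since slide 1 holds both. In aligned scanner values the SD ratio is 1 by construction, and it was 0.700 to 1.29 without 1 array. In the table the SD of nimesulide and control was 0.69, which makes the ratio 0.319, and 0.283 to 0.574 without 1 array. The ratio of 0.253 is consistent with an alignment of slides 2 and 3 with each other, but that leaves the likeness to ketoprofen open.

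Other splits of the 8 arrays into 4 and 4 were counted for each comparison. For ketoprofen against control the count called was 0, which all 35 of the 35 splits reach by construction, so it says nothing about chance. The highest of the others gave 108. That split differs from the real one by the exchange of control 1 and ketoprofen 3. It follows the first principal component, which cut across the 2 groups. Control 1 (-190.4) and ketoprofen 1 (-152.6), 2 (-6.2) and 4 (-70.9) were the only arrays with negative values on it. What underlies that component was not tested. For nimesulide against control 4 of the 35 splits gave as many as the 2 called, and the highest other gave 4. For nimesulide against ketoprofen 9 of the 35 gave as many as the 1 called, and the highest other gave 5. Chance was thus not excluded for either count with nimesulide in the design's fit. At an unadjusted p under 0.05, 5 of the 35 splits gave at least the 3193 probes between ketoprofen and control (highest other 4244). For nimesulide it was 2 of 35 for the 2523 against control (highest other 2649) and 2 of 35 for the 3003 against ketoprofen (highest other 3901). In the fit of the 8 arrays alone, 7 of 35 splits gave as many as the 6 between ketoprofen and control (highest other 117). Only the real split gave 16 between nimesulide and control (highest other 11). The real split of nimesulide and control is also the split by slide.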
